A study of Mus musculus with 12 samples.

How the data were processed

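The data were RNA-seq read counts per gene from 12 mouse lung libraries, 6 from mice of a hyperoxia model of acute lung injury (HALI) and 6 controls. Per the labels, RNA was extracted from lung with TRIzol and polyadenylated RNA was selected with oligo(dT) beads from 1 μg of total RNA. Per the labels' protocols, the exposed mice were kept in at least 90% oxygen for 23.5 hours a day. The labels place HALI in a field named genotype, although the protocol describes an exposure, so HALI is read here as the exposure. Per the submitters' processing notes, Trim Galore 0.6.4 and STAR 2.7.10b were used. The deposited file holds raw counts, whole numbers with column totals that differ between libraries. The counting tool, its strand setting, the genome build and the annotation release are not given in the sources used here, so no coordinates are printed.

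The file held 56953 Ensembl gene identifiers with version numbers. Symbols and gene types came from a reference annotation matched on the identifier without its version, since only 35 matched with it. A symbol was found for 52029 identifiers, and 399 of the tested genes had none. A count in at least 1 library was found for 38118 identifiers. Total counts ranged from 9.58 to 33.7 M per library. Counts per M of counts (CPM) used these totals multiplied by the normalization factor of each library, and log2 CPM used a prior count of 2.

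Groups came from the labels. The choices of test, filter, alternatives, gene lists and rule for naming genes were made before the data were examined, except where the text says otherwise. Genes were kept by the filterByExpr function of edgeR 4.0.16 on the group, which left 18701. TMM factors ranged from 0.969 to 1.02. HALI was compared with control by the robust quasi-likelihood F-test of edgeR, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of F. Libraries that share a replicate number were treated as unpaired. The residual correlation between the libraries of a shared number ran from -0.244 to 0.205, and 1 of 6 was above 0.1. Chi-square values per degree of freedom between the 30 pairs of libraries within a group ran from 7.65 to 46.7, so no library was a copy of another.

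In all, 45 gene lists were fixed (pathways, cell types and tissues next to the lung), of which 44 had the 3 measured members a test needs. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, adjusted over the lists. Members were also counted after adjustment over the list alone, from the p-values of the same fit. A few lists share genes with another, and lung cells of several types express many of the markers. Alternatives were other scalings (DESeq2 size factors, upper quartile, library size only), no filter, a stricter filter of 1 CPM in 6 libraries, DESeq2 1.42.0, and limma-voom with quality weights. Further ones were the replicate number as a block, a threshold of 0.01, each library left out in turn, an estimated correlation in camera, and fry. Principal components were repeated with a prior count of 0.5 and over the 500 most variable genes. Alternatives chosen after the data were seen were the score of the cardiac markers as a covariate, leaving out control replicate 5 and HALI replicate 5 together, and an exact permutation of the mean log2 CPM of each list over all 924 assignments of the labels. From the 462 divisions of the 12 libraries into 6 and 6, the real one included, 100 were refitted.

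The rule for naming genes took the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and no overlap between groups, predicted genes left out. It added for each list up to 3 called members of smallest p, or the 2 of smallest p where no member was called, with the best member called in the opposite direction. It also took the 5 genes of highest mean CPM. Genes named outside the rule are marked in the text as chosen after their values were seen.

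The tools were tested on simulated data drawn from the mean expression of the control libraries, with the dispersions and library sizes of the real data and changes planted in 200 genes. At a planted log2 change of 1, edgeR recovered 91% of 100 genes and at 0.5 it recovered 48%, with 11 false among 150 calls (7.33%). DESeq2 recovered 93% and 59% with 19.6% false, and limma-voom 84% and 45% with 5.84% false. Of 40 simulated lists of 15 genes camera called the 10 shifted by 0.5 and no others, with the preset and with the estimated correlation. The simulated genes were drawn independently of each other. The simulation therefore could not show how either version of camera behaves on lists of correlated genes, as the real lists are. Computation used R 4.3.3 and Python 3.11.15.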

Results

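The data were read counts per gene from polyA-selected RNA of whole mouse lung, in 6 libraries from mice kept in at least 90% oxygen for 23.5 hours a day and 6 control libraries. The oxygen exposure is a model of hyperoxia-induced acute lung injury (HALI), and the labels give HALI or control as the only difference between the groups. The labels state that 6 mice were exposed. They do not state the length of the exposure, the sex or age of the mice, or whether each control library came from its own animal. Total counts per library were 33.7, 24.9, 28.3, 9.58, 31.3 and 28.0 M for control replicates 1 to 6 and 25.1, 10.4, 16.7, 32.0, 9.92 and 32.5 M for HALI replicates 1 to 6. A count of 3 in a library corresponded to 0.0889 to 0.313 per M of its unscaled total, which covers counting error only, and counts per M below (CPM) include the scaling factor. Between 25253 and 30340 genes had a count in a control library and between 25537 and 29563 in a HALI library. Mitochondrially encoded transcripts made up 1.95 ± 0.239% of the counts in control and 1.97 ± 0.114% in HALI libraries (SD, n = 6 each). The 5 most abundant genes took 5.63 ± 0.577% of the counts in control and 3.88 ± 0.289% in HALI libraries.

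All 6 HALI libraries lay apart from all 6 control libraries on the first principal component of expression, which held 33.2% of the variance. Control libraries had scores of -39.7 to -14.4 and HALI libraries 13.7 to 42.4, a gap of 34.3% of the whole range. The second component, with 18.2% of the variance, spread the libraries within each group. Over the 500 most variable genes the groups overlapped on the first component by 6.10% of its range (a gap of -6.10%). The Spearman correlation across genes had a median of 0.989 between libraries of a group (0.978 to 0.994) and of 0.980 between groups (0.972 to 0.984), and genes are not independent replicates.

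**Figure D1:**
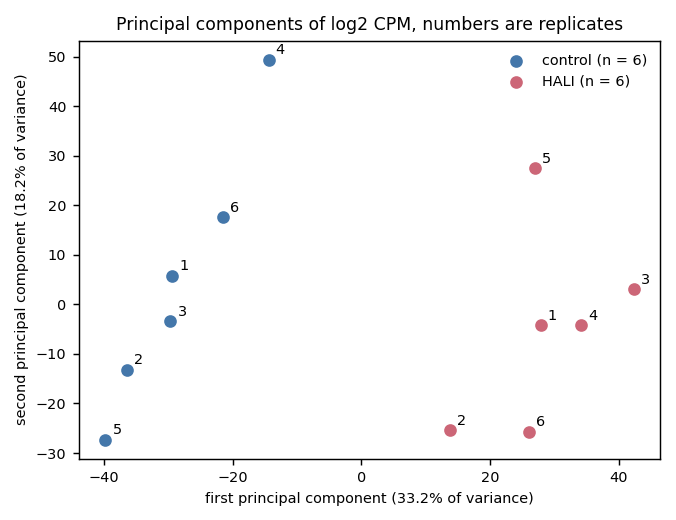
Scores of the 12 libraries on the first (33.2% of variance) and second (18.2%) principal components of log2 CPM, 6 control and 6 HALI, with replicate numbers beside the points. Control libraries lie between -39.7 and -14.4 on the first component and HALI libraries between 13.7 and 42.4.

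The comparison of HALI with control lungs asked which genes differ in expression after hyperoxia. In HALI lungs, 14 of 18 p53 targets and 13 of 18 targets of the oxidant-response factor NRF2 were called higher, while 10 of 11 B cell genes and 13 of 20 interferon-stimulated genes were called lower. Gdf15 (Ensembl ENSMUSG00000038508), a stress-induced cytokine, stood at 0.903 ± 0.27 CPM in control lungs and 43.5 ± 20.1 CPM in HALI lungs (mean ± SD, n = 6 libraries per group), a log2 fold change of 5.67 ± 0.44 (SE). Sftpa1 (ENSMUSG00000021789), which encodes surfactant protein A, stood at 4279 ± 687 CPM in control lungs and 2048 ± 231 CPM in HALI lungs, a log2 fold change of -1.06 ± 0.11. Of 18701 genes tested, 2779 (14.9%) were higher and 2641 (14.1%) lower in HALI lungs at an adjusted p below 0.05, and 268 were at least 2-fold higher and 412 at least 2-fold lower. For 2363 genes (12.6%) every HALI library lay on the same side of every control library, against 0.216% by chance.

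Higher genes made up 51.3% of the calls with the scaling used here and 38.9% with upper-quartile scaling, which called 2121 genes higher and 3334 lower. The p-values measure the spread between libraries, 6 of them from the exposed mice, and changes are relative to the other genes, whose median log2 fold change was -0.02.

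The largest rises among genes with no overlap between the groups were in Gdf15, Adm2, Eda2r and Slc7a11. Adm2 (ENSMUSG00000054136), a peptide hormone of the adrenomedullin family, had 16 counts over the 6 control libraries and 501 over the 6 HALI libraries, a log2 fold change of 5.14 ± 0.32 (adjusted p = 3.2e-07). Eda2r (ENSMUSG00000034457), a receptor of the TNF receptor family and a p53 target, stood at 2.84 ± 0.895 CPM in control lungs and 32 ± 11.6 CPM in HALI lungs (adjusted p = 5.5e-06). Slc7a11 (ENSMUSG00000027737), the cystine transporter that feeds glutathione synthesis, stood at 3.99 ± 2.47 CPM in control lungs and 43.3 ± 14 CPM in HALI lungs (adjusted p = 4.6e-05). Mthfd2 (ENSMUSG00000005667) and Aldh1l2, enzymes of mitochondrial folate metabolism, had log2 fold changes of 2.65 ± 0.13 and 2.85 ± 0.25. The other large rises were Spink5 (2.61 ± 0.23), Nr1d1 (2.61 ± 0.35), Psrc1 (2.58 ± 0.19) and Tenm4 (2.38 ± 0.22), given as log2 fold change ± SE.

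The 10 largest falls without overlap were in Phyhip, Thrsp, Cyp1a1, Entpd8, Slurp1, Fam124b, Eppin, Chad, Rasd1 and Lrrc26, with log2 fold changes from -2.95 to -2.10. Entpd8, an ectonucleotidase, stood at 2 ± 0.645 CPM in control lungs and 0.322 ± 0.139 CPM in HALI lungs (adjusted p = 1.4e-05), and Lrrc26 stood at 10.7 ± 2.16 CPM in control lungs and 2.57 ± 0.998 CPM in HALI lungs (adjusted p = 3e-05). Cyp1a1, the aryl hydrocarbon receptor target that oxidises many foreign compounds, stood at 129 ± 147 CPM in control lungs and 20 ± 4.64 CPM in HALI lungs. Control replicate 2 held 426 CPM of Cyp1a1, and without it the log2 fold change was -1.79 in place of -2.69. Thrsp, a regulator of lipid synthesis, had a log2 fold change of -2.70 ± 0.57 with all libraries and of -1.90 without control replicate 5.

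**Figure D2:**
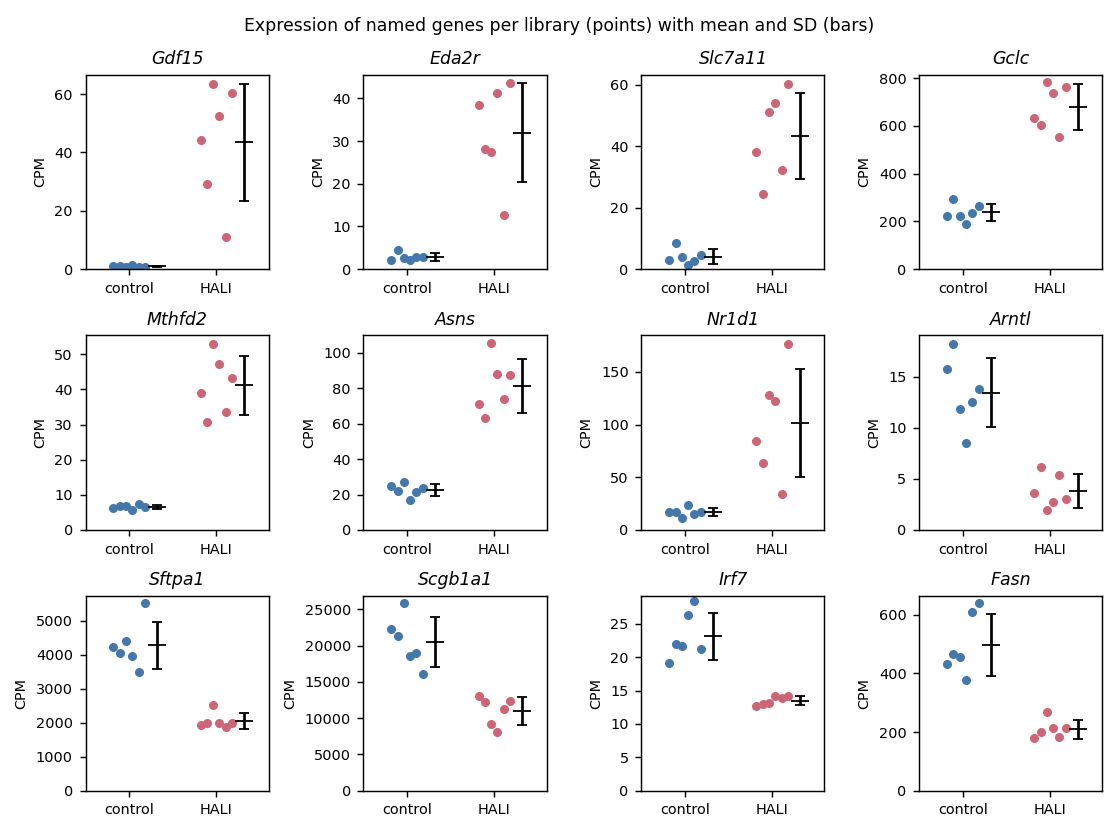
Counts per M of 12 genes in each library (points, 6 control and 6 HALI), with the group mean and SD (black bars) and every axis starting at 0. Gdf15, Eda2r, Slc7a11, Gclc, Mthfd2, Asns and Nr1d1 are higher and Arntl, Sftpa1, Scgb1a1, Irf7 and Fasn lower in every HALI library than in every control library.

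Most of the NRF2 and p53 targets measured were higher in HALI lungs. Of 18 measured NRF2 targets, 13 rose and 5 did not pass (14 rose adjusted over the list alone), with a median log2 fold change of 0.72. Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, stood at 238 ± 35.3 CPM in control lungs and 680 ± 95.3 CPM in HALI lungs, and the other examples were Gpx2 (1.68 ± 0.17) and Txnrd1 (1.15 ± 0.10) (log2 fold change ± SE). The list passed the camera test at adjusted p = 4.2e-10, with adjusted p = 0.54 with an estimated correlation. Of 18 p53 targets, 14 rose, Fas fell and 3 did not pass, the same counts as adjusted over the list alone, with a median of 1.21. The pro-apoptotic genes Bax (14.3 ± 1.3 CPM in control lungs and 40.2 ± 6.54 CPM in HALI lungs) and Tnfrsf10b (2.21 ± 0.15) and the nuclease gene Aen (1.66 ± 0.10) rose, and Fas, a death receptor, had -0.54 ± 0.10. This list had camera adjusted p = 2.5e-11, and adjusted p = 0.54 with an estimated correlation.

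In the integrated stress and unfolded protein response, 12 of 18 genes rose, 5 fell and 1 did not pass, the same counts as adjusted over the list alone. The members that rose included Mthfd2 (2.65 ± 0.13), Trib3 (2.02 ± 0.17) and Asns (1.84 ± 0.13), targets of the transcription factor ATF4, where Asns makes asparagine. Those that fell included Hyou1 (-0.39 ± 0.07), Hspa5 (-0.47 ± 0.08), Sdf2l1 (-0.85 ± 0.19) and Pdia4 (-0.31 ± 0.08), genes of protein folding in the endoplasmic reticulum. The fifth that fell was Xbp1 (-0.19 ± 0.07), a transcription factor gene of the unfolded protein response. Of the 5 that fell, Hyou1 was named by rule and the others after their values were seen. The median log2 fold change was 0.75 and camera gave adjusted p = 0.00025, with adjusted p = 0.74 with an estimated correlation. Of 12 iron-handling and ferroptosis genes, Ftl1, Ptgs2, Slc40a1 and Fth1 rose, Lpcat3 fell and 7 did not pass (4 and 1 adjusted over the list alone, median 0.06, camera adjusted p = 0.091). The ferritin light chain gene Ftl1 (1.31 ± 0.10), the iron exporter gene Slc40a1 (1.25 ± 0.17) and the cyclooxygenase gene Ptgs2 (1.84 ± 0.22) had the largest changes, and reads of Ftl1 are not separable here from those of its near-copies. Fth1 (0.27 ± 0.09) was chosen after its values were seen. Fth1 missed the threshold without control replicate 5 or HALI replicate 1 or 3 (adjusted p up to 0.072). Xbp1 missed the threshold without any library other than control replicate 3 or 5 or HALI replicate 3 (adjusted p up to 0.10).

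Of the 4 metallothionein and superoxide dismutase genes measured, only Mt1 passed, at 35.2 ± 2.47 CPM in control lungs and 73.1 ± 15.5 CPM in HALI lungs, and adjusted over the list alone Mt1 rose and Sod1 (-0.17 ± 0.07, chosen after its values were seen) fell (median 0.11, camera adjusted p = 0.54). Over all genes Sod1 passed with upper-quartile scaling (adjusted p = 0.029), in limma-voom (0.031) and without control replicate 5 (0.037) or HALI replicate 5 (0.032). Of 14 hypoxia targets, Ankrd37, Pgk1 and Pfkfb3 rose, Bnip3 fell and 10 did not pass (3 and 1 adjusted over the list alone, median 0.06, camera adjusted p = 0.36). The log2 fold changes were Ankrd37 (1.79 ± 0.16), Pgk1 (0.28 ± 0.06), Pfkfb3 (0.28 ± 0.10) and Bnip3 (-0.38 ± 0.08). Pfkfb3 was chosen after its values were seen. Of 10 heat shock genes, 1 was called higher, 2 lower and 7 did not pass (2 higher and 3 lower adjusted over the list alone, median 0.11, camera adjusted p = 0.87). They were Dnajb1 (0.61 ± 0.19), Hspb1 (-0.86 ± 0.25) and Hspa8 (-0.41 ± 0.11). Dnajb1 passed without HALI replicate 2, HALI replicate 5 or control replicate 4 and missed the threshold without any of the other 9 libraries (adjusted p up to 0.071), and Hspb1 missed it without control replicate 2 (adjusted p = 0.055). Pfkfb3 missed the threshold without any library other than control replicate 6 or HALI replicate 2 or 5 (adjusted p up to 0.10).

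Of 18 measured genes for cytokines, chemokines and acute-phase proteins, 6 rose and 12 did not pass (7 rose adjusted over the list alone), with a median log2 fold change of 0.77. The cytokine gene Il6 had 18 counts over the 6 control libraries and 221 over the 6 HALI libraries, and HALI replicate 6 held 150 of the latter. Its log2 fold change was 3.70 ± 0.67, and 2.73 without HALI replicate 6. The neutrophil-attracting chemokine gene Cxcl1 (1.57 ± 0.31) and Ccl20 (2.11 ± 0.47) also rose. Camera gave adjusted p = 0.037 for the list, 0.071 without HALI replicate 6, and adjusted p = 0.74 with an estimated correlation. Of 12 immediate early genes, 5 rose and 7 did not pass (8 rose adjusted over the list alone, median 0.66). They were the transcription factor genes Nr4a1 (2.07 ± 0.39), Atf3 (1.66 ± 0.33) and Junb (0.83 ± 0.23) and, chosen after their values were seen, Ier2 (0.52 ± 0.18) and Egr2 (0.73 ± 0.26). The camera test gave adjusted p = 0.0011 for these, with adjusted p = 0.74 with an estimated correlation, and Junb had 0.53 and Egr2 0.39 without HALI replicate 6. Ier2 missed the threshold without any library other than control replicate 4 or HALI replicate 2 or 4 (adjusted p up to 0.081). Egr2 missed the threshold without any library other than control replicate 4 or HALI replicate 1, 2 or 5 (adjusted p up to 0.095).

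In coagulation and fibrinolysis, 7 of 12 genes rose, 4 fell and 1 did not pass, the same counts as adjusted over the list alone (median 0.43). The tissue factor gene F3 stood at 81.5 ± 6.99 CPM in control lungs and 153 ± 21.4 CPM in HALI lungs, and Plau had a log2 fold change of 1.29 ± 0.19, while F13a1, a factor that crosslinks fibrin, had -0.89 ± 0.16. The other genes that fell, chosen after their values were seen, were Thbd (-0.63 ± 0.14), F10 (-0.72 ± 0.18) and Vwf (-0.53 ± 0.16). Vwf missed the threshold without control replicate 2 or 6 or HALI replicate 1, 2 or 6 (adjusted p up to 0.063). For the list camera gave adjusted p = 0.066, which passed without HALI replicate 5 (0.029) and without control replicate 2 (0.045). Of 7 endothelial adhesion genes, Icam1, Sele and Vcam1 rose and 4 did not pass, the same counts as adjusted over the list alone (median 0.36, camera adjusted p = 0.077, 0.045 without control replicate 2 and 0.036 without control replicate 4). Icam1, a ligand for leukocyte integrins, stood at 315 ± 45.8 CPM in control lungs and 540 ± 65.9 CPM in HALI lungs. Vcam1 (0.36 ± 0.11) missed the threshold without control replicate 1 or HALI replicate 1, 3, 4 or 6 (adjusted p up to 0.064) and with upper-quartile scaling (0.053). Of 12 genes of the inflammasome and pyroptosis list, Mlkl (0.85 ± 0.10) and Casp4 (0.63 ± 0.13) rose and 10 did not pass. The counts adjusted over the list alone were the same. Mlkl belongs to necroptosis, another form of cell death. The median of the list was -0.12, the mean 0.02 and the camera direction lower (adjusted p = 0.9).

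Interferon-stimulated genes were lower in HALI lungs. Of 20 measured, 13 fell and 7 did not pass (15 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.47. Irf7, a transcription factor of the interferon response, stood at 23.1 ± 3.49 CPM in control lungs and 13.5 ± 0.673 CPM in HALI lungs, and Oasl2 (-0.73 ± 0.09) and Xaf1 (-0.44 ± 0.06) fell as well (log2 fold change ± SE). By camera the list had adjusted p = 2.2e-05, with adjusted p = 0.72 with an estimated correlation. Of 15 genes of the interferon-gamma and MHC class II list, only Cxcl10 passed, with a rise of 1.63 ± 0.41, and 14 did not, as when adjusted over the list alone (median -0.14, camera adjusted p = 0.32).

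Circadian clock genes differed strongly between the groups. Of 16 measured, 10 rose, 3 fell and 3 did not pass (11 rose and 4 fell adjusted over the list alone), with a median log2 fold change of 0.42. The clock repressor genes Nr1d1 (2.61 ± 0.35), Nr1d2 (1.13 ± 0.14), Bhlhe40 (1.32 ± 0.16) and Bhlhe41 (1.34 ± 0.17) rose, and Arntl, which encodes the activator BMAL1, fell from 13.5 ± 3.36 CPM to 3.81 ± 1.62 CPM. HALI replicate 5 lay closer to the controls than the other HALI libraries for several of them, with 34.1 CPM of Nr1d1 against a mean of 115 CPM in the other HALI and 16.9 CPM in the control libraries. For Dbp, chosen after its values were seen, it held 8.58 CPM against 52.4 and 8.76 CPM. The adjusted p by camera was 0.0051, with adjusted p = 0.72 with an estimated correlation. The hour at which the lungs were taken is not stated. Of 11 glucocorticoid targets, Pdk4 (0.68 ± 0.16) rose, Sult1a1 (-1.13 ± 0.17) and Tsc22d3 (-0.43 ± 0.13) fell and 8 did not pass, the same counts as adjusted over the list alone (median -0.02, camera adjusted p = 0.82).

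In the lipid and cholesterol synthesis list, 9 of 19 fell, 3 rose and 7 did not pass (10 fell and 3 rose adjusted over the list alone, median -0.28). Fasn, fatty acid synthase, stood at 497 ± 104 CPM in control lungs and 210 ± 32 CPM in HALI lungs, the desaturase genes Scd1 (-1.18 ± 0.18) and Scd2 (-0.56 ± 0.10) fell, and Cyp51, an enzyme of cholesterol synthesis, rose (0.53 ± 0.10), as did Sqle (0.29 ± 0.10) of the same pathway, chosen after its values were seen. Sqle missed the threshold without control replicate 1 or HALI replicate 3 or 6 (adjusted p up to 0.076). Camera gave adjusted p = 0.029, 0.051 without control replicate 6, and adjusted p = 0.76 with an estimated correlation. Of 22 nuclear genes for oxidative phosphorylation, 8 rose by little and 14 did not pass (9 rose adjusted over the list alone, median 0.14), among them Atp5b (0.41 ± 0.08), Atp5a1 (0.33 ± 0.07) and Sdhb (0.30 ± 0.07). The camera test gave adjusted p = 0.002, with adjusted p = 0.74 with an estimated correlation. 0 of the 10 mitochondrially encoded genes passed in edgeR, where 1 had an unadjusted p below 0.05, while DESeq2 called mt-Co2 higher and limma-voom called 0. The list had a median of 0.11 and camera adjusted p = 0.53, and mt-Co2 (0.39 ± 0.16) passed without HALI replicate 6 (adjusted p = 0.038).

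Of 28 cell cycle genes, Mcm3 rose, Mcm7, Kif20a and Aurka fell and 24 did not pass, the same counts as adjusted over the list alone, with a median log2 fold change of -0.34 and camera adjusted p = 0.056. The replication helicase genes had opposite signs, Mcm7 (-0.43 ± 0.07) and Mcm3 (0.42 ± 0.09), and the mitotic kinesin gene Kif20a had -0.66 ± 0.17, and the mitotic kinase gene Aurka -0.51 ± 0.16 (chosen after its values were seen). The camera p ran from 0.014 to 0.28 when each library was left out and passed without control replicate 1, 2, 4 or 6 or HALI replicate 1 or 2. In the extracellular matrix list, Ccn2, Thbs1, Tnc and Timp1 rose and 15 of 19 did not pass (3 rose adjusted over the list alone, median 0.35). Their changes were Ccn2 (1.15 ± 0.16), Thbs1 (1.23 ± 0.24), Tnc (1.18 ± 0.33) and Timp1 (1.40 ± 0.46), where Timp1 was chosen after its values were seen. For the list camera gave adjusted p = 0.031, but 0.062 without control replicate 3, 0.051 without control replicate 6, 0.071 without HALI replicate 6 and 9.1e-05 without HALI replicate 5, and adjusted p = 0.76 with an estimated correlation. Timp1 missed the threshold without any library other than control replicate 2 or 6 or HALI replicate 3, 4 or 5 (adjusted p up to 0.093). Aurka missed the threshold without control replicate 2 or 3 or HALI replicate 4 or 6 (adjusted p up to 0.066). The mean log2 CPM of this list was 6.26 in HALI replicate 5 and 7.20 to 7.60 in the other HALI libraries.

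**Figure D3:**
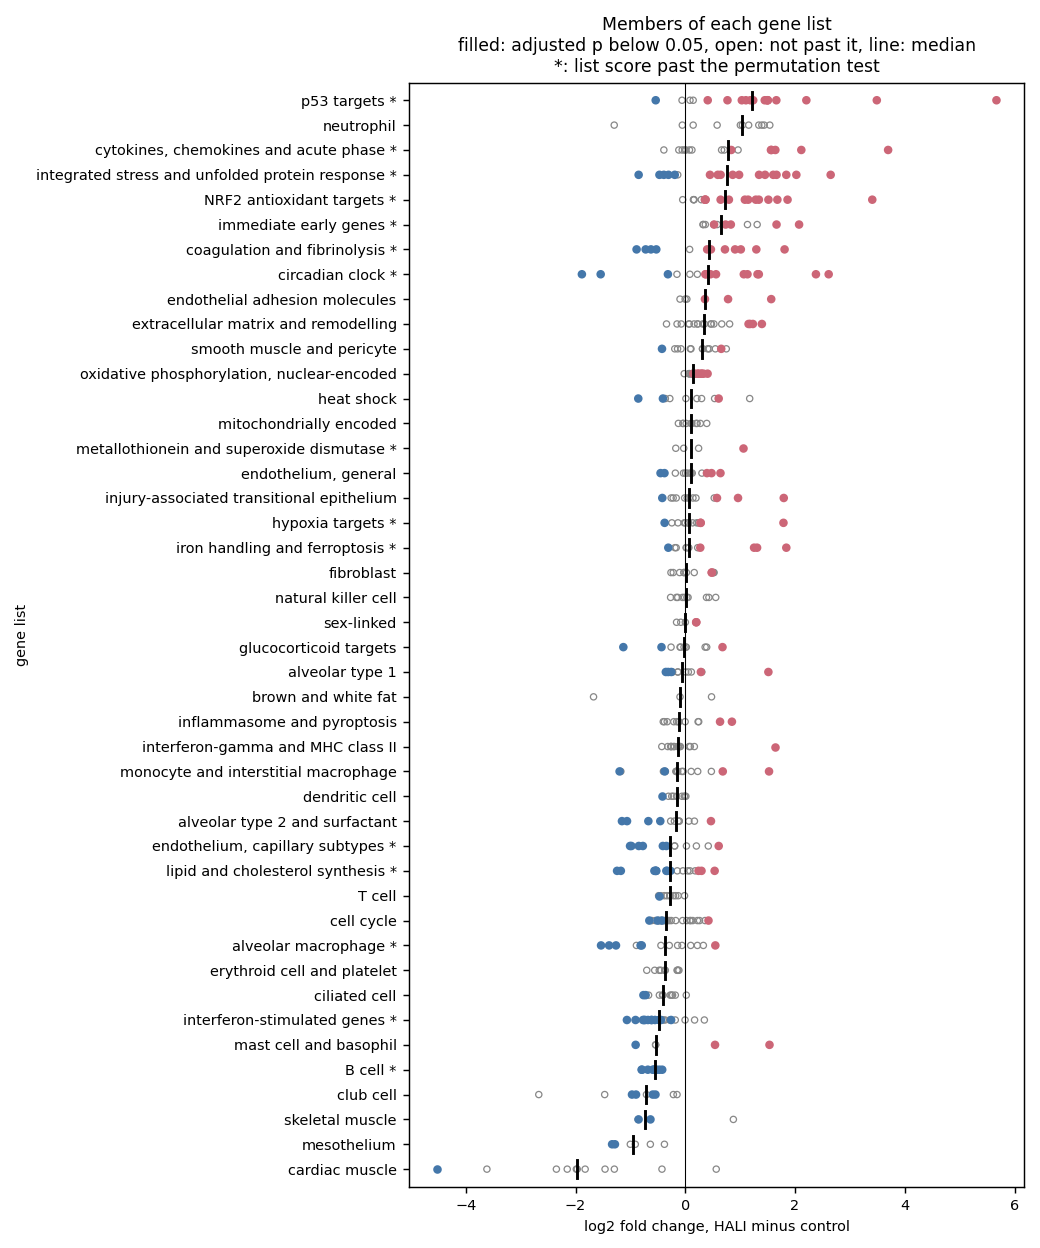
Log2 fold changes (HALI minus control) of the members of the 44 gene lists tested, sorted by median (black lines); filled points passed an adjusted p of 0.05 and open points did not. The p53 targets have a median of 1.21 and the cardiac muscle list one of -1.97, and stars mark the 15 lists whose score passed the permutation test.

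The club cell secretory protein gene Scgb1a1, the gene with the most counts, stood at 20532 ± 3423 CPM in control lungs and 11011 ± 1959 CPM in HALI lungs (n = 6 each, log2 fold change -0.90 ± 0.14). Of 9 club cell genes, Scgb1a1, Cckar, Hp and Cyp2f2 fell and 5 did not pass, the same counts as adjusted over the list alone (median -0.71). The log2 fold changes were Cckar (-0.97 ± 0.16), Hp (-0.54 ± 0.16) and Cyp2f2 (-0.59 ± 0.18). Cyp2f2 was chosen after its values were seen. By camera the list had adjusted p = 0.0088, with adjusted p = 0.74 with an estimated correlation. Of 11 ciliated cell genes, Tppp3 (-0.72 ± 0.10) and Dynlrb2 (-0.76 ± 0.21) fell and 9 did not pass, the same counts as adjusted over the list alone (median -0.41, camera adjusted p = 0.051, 0.0035 to 0.11 when each library was left out, below 0.05 without control replicate 2, 4 or 6 or HALI replicate 1, 2 or 6). Heart muscle transcripts also differed between libraries, with a mean log2 CPM of the cardiac list of 0.72 to 5.62 in control and 0.90 to 2.98 in HALI libraries. With that score as a covariate, added after the data were seen, Cyp2f2 had -0.42 ± 0.16 (adjusted p = 0.075) and Hp -0.45 ± 0.16 (adjusted p = 0.057), while the other 4 club and ciliated genes still passed, Dynlrb2 with a smaller change of -0.50 ± 0.16 (adjusted p = 0.034). Among the genes named in other groups, that fit ended the calls of Aurka, Calcrl, Cd3e, Cldn5, Clic5, Cxcl15, Ddx3y, Dnajb1, Egfl7, Egr2, Eif2s3y, Fth1, Ier2, Ly6c2, Ms4a7, Pfkfb3, Scnn1g, Tcf21, Themis and Tnni2.

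Of 12 alveolar type 2 and surfactant genes, 4 fell, Cxcl15 rose and 7 did not pass (5 fell and 1 rose adjusted over the list alone, median -0.17, camera adjusted p = 0.051). The surfactant genes Sftpa1 (-1.06 ± 0.11), Sftpd (-0.67 ± 0.12) and Sftpc (-0.46 ± 0.14) and the lysozyme gene Lyz1 (-1.16 ± 0.18) fell, where Lyz1 and Lyz2 (-0.89 ± 0.13) are near-copies whose reads are not fully separable. Sftpc missed the threshold without HALI replicate 4 (adjusted p = 0.051), and Cxcl15 (0.47 ± 0.15) without control replicate 1, 4 or 5 or HALI replicate 3 or 6 (up to 0.063). The camera p of the list ran from 0.0088 to 0.14 when each library was left out and passed without control replicate 1, 2, 4 or 5 or HALI replicate 3, 4 or 6. Of 12 alveolar type 1 genes, 2 rose, 3 fell and 7 did not pass (3 and 3 adjusted over the list alone), with a median of -0.06, a mean of 0.07 and a camera direction of lower (adjusted p = 0.98). Igfbp2 rose from 70.5 ± 18.7 CPM to 201 ± 58.7 CPM, and Emp2 (-0.31 ± 0.08) and Hopx (-0.36 ± 0.11) fell. Scnn1g (0.28 ± 0.09) rose and Clic5 (-0.26 ± 0.09) fell, both chosen after their values were seen. Hopx missed the threshold without control replicate 3 or 6 or HALI replicate 2, 4 or 6 (adjusted p up to 0.058). Scnn1g missed the threshold without control replicate 1 or 5 or HALI replicate 1, 3, 4 or 5 (adjusted p up to 0.069). Clic5 missed the threshold without any library other than control replicate 4 or HALI replicate 4 (adjusted p up to 0.10). Of 13 genes of injury-associated transitional epithelium, Lgals3, Areg and Cldn4 rose, Sfn fell and 9 did not pass, the same counts as adjusted over the list alone (median 0.07, camera adjusted p = 0.36), with Lgals3 (0.96 ± 0.13), Areg (1.79 ± 0.31), Cldn4 (0.58 ± 0.19) and Sfn (-0.42 ± 0.11). Cldn4 was chosen after its values were seen. Cldn4 missed the threshold without any library other than control replicate 1 or 5 or HALI replicate 1, 2 or 4 (adjusted p up to 0.083).

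Capillary endothelial markers were more often lower than higher. Of 12 measured, 6 fell, Apln rose and 5 did not pass (6 fell and 3 rose adjusted over the list alone), with a median log2 fold change of -0.27. Hpgd, which degrades prostaglandins, stood at 799 ± 114 CPM in control lungs and 467 ± 70.4 CPM in HALI lungs, the endothelin receptor gene Ednrb had -1.01 ± 0.16 and Sgk3 -0.35 ± 0.06, while Apln rose (0.61 ± 0.15). The adjusted p by camera was 0.063, which passed without control replicate 3 (0.034) or control replicate 6 (0.045). Of 13 general endothelial genes, 3 rose, 2 fell and 8 did not pass, the same counts as adjusted over the list alone (median 0.10, camera adjusted p = 0.49). They were Emcn (0.48 ± 0.09), Cldn5 (0.39 ± 0.13), Egfl7 (0.64 ± 0.21), Calcrl (-0.45 ± 0.13) and Ptprb (-0.38 ± 0.12), of which Cldn5 and Egfl7 were chosen after their values were seen. Ptprb missed the threshold without control replicate 1, 2 or 6 or HALI replicate 1, 3 or 6 (adjusted p up to 0.075). Cldn5 missed the threshold without control replicate 1, 3, 5 or 6 or HALI replicate 1 or 5 (adjusted p up to 0.072). Egfl7 missed the threshold without any library other than control replicate 4 or HALI replicate 2 or 4 (adjusted p up to 0.072). Of 11 fibroblast genes, Npnt (0.48 ± 0.13) and Tcf21 (0.48 ± 0.15) rose and 9 did not pass, the same counts as adjusted over the list alone, with a median of 0.02 that was -0.03 with upper-quartile scaling (camera adjusted p = 0.36), and Tcf21 missed the threshold without control replicate 1, 2, 3, 5 or 6 (up to 0.059). Of 13 smooth muscle and pericyte genes, Trpc6 (0.65 ± 0.13) rose, Cox4i2 (-0.43 ± 0.13) fell and 11 did not pass, the same counts as adjusted over the list alone (median 0.31, camera adjusted p = 0.26), and Cox4i2 missed the threshold without control replicate 2 or HALI replicate 2, 4 or 6 (up to 0.058).

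B cell transcripts were lower in HALI lungs. Of 11 genes, 10 fell and 1 did not pass (11 fell adjusted over the list alone), with a median log2 fold change of -0.55 and examples of Ms4a1 (-0.80 ± 0.17), Pax5 (-0.79 ± 0.17) and Cd22 (-0.55 ± 0.12). Camera gave adjusted p = 0.00021, with adjusted p = 0.74 with an estimated correlation. Of 11 T cell genes, only Cd3e fell (-0.48 ± 0.15) and 10 did not pass, and adjusted over the list alone 0 fell in edgeR, where 4 had an unadjusted p below 0.05, DESeq2 called 2 lower and limma-voom 3 (median -0.29). The camera test gave adjusted p = 0.031, but 0.062 without control replicate 3, 0.056 without HALI replicate 3 and 0.074 without HALI replicate 6, and adjusted p = 0.76 with an estimated correlation. Cd3e missed the threshold without control replicate 2 or 3 or HALI replicate 1, 3 or 6 (adjusted p up to 0.070). Of 14 alveolar macrophage genes, 5 fell, Pparg rose and 8 did not pass (7 fell and 1 rose adjusted over the list alone, median -0.37). The ribonuclease genes Ear1 (-1.54 ± 0.17) and Ear2 (-1.39 ± 0.12), near-copies of each other, and Cidec (-1.26 ± 0.16) fell, and Pparg had 0.55 ± 0.11. The other 2 that fell, chosen after their values were seen, were Siglecf (-0.82 ± 0.16) and Chil3 (-0.79 ± 0.17). For the list camera gave adjusted p = 0.031, with adjusted p = 0.74 with an estimated correlation.

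The 11 neutrophil genes measured differed less between groups than between HALI libraries. In edgeR 0 of the 11 passed, also adjusted over the list alone, and 0 had an unadjusted p below 0.05, with 0 called by DESeq2 and 0 by limma-voom. The median log2 fold change was 1.04 and the mean 0.75, while the camera direction was lower (adjusted p = 0.56). HALI replicate 5 had a mean log2 CPM of these genes of 5.48, against 1.72 to 2.10 in the other HALI and 2.36 to 3.04 in the control libraries. Without HALI replicate 5 camera gave adjusted p = 0.0015 in the direction of lower in HALI. The chemokine receptor gene Cxcr2 then had a log2 fold change of -0.57 (adjusted p = 0.021) in place of 1.44 ± 0.89, and Retnlg -1.02 (adjusted p = 0.0057) in place of 1.54 ± 1.05.

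Of 16 monocyte and interstitial macrophage genes, Gpnmb and Ms4a7 rose, Arg1 and Ly6c2 fell and 12 did not pass (2 rose and 4 fell adjusted over the list alone, median -0.15, camera adjusted p = 0.83). Gpnmb, a glycoprotein of phagocytes, stood at 17.6 ± 1.95 CPM in control lungs and 50.7 ± 11.5 CPM in HALI lungs, and the others had Ms4a7 (0.68 ± 0.22), Arg1 (-1.20 ± 0.23) and Ly6c2 (-0.38 ± 0.11). Ms4a7 was chosen after its values were seen. Ms4a7 missed the threshold without control replicate 2 or 4 or HALI replicate 3, 4 or 6 (adjusted p up to 0.081). Of 9 dendritic cell genes, Clec9a fell (-0.43 ± 0.09) and 8 did not pass, as when adjusted over the list alone (median -0.16, camera adjusted p = 0.36). Of 10 natural killer cell genes 0 passed in edgeR, also adjusted over the list alone, where 3 had an unadjusted p below 0.05, while DESeq2 called 2 and limma-voom 3 higher. Klra8 (0.55 ± 0.21), of a family of near-copies, and Prf1 (0.39 ± 0.16) had adjusted p = 0.034 and 0.018 without HALI replicate 5, and Klra8 had 0.030 without control replicate 3. The median was 0.01, and -0.04 with upper-quartile scaling (camera adjusted p = 0.7). Of 5 mast cell and basophil genes, Ms4a2 (1.53 ± 0.42) and Cpa3 (0.54 ± 0.17) rose, Kit (-0.91 ± 0.15), which lung endothelium also expresses, fell and 2 did not pass, the same counts as adjusted over the list alone, with a median of -0.54, a mean of 0.02 and a camera direction of lower (adjusted p = 0.83). Cpa3 missed the threshold without control replicate 1, 5 or 6 or HALI replicate 1, 2 or 6 (adjusted p up to 0.074) and with upper-quartile scaling (0.051).

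**Figure D4:**
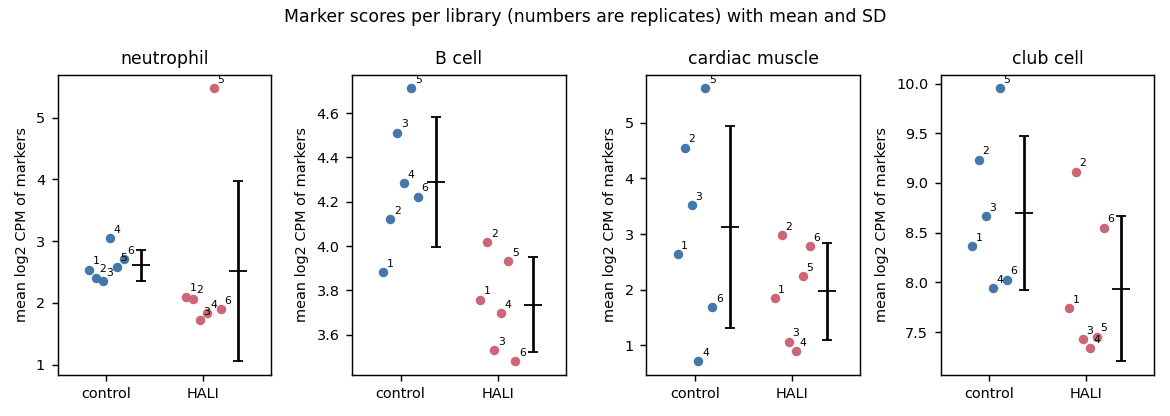
Mean log2 CPM of the markers of neutrophils, B cells, cardiac muscle and club cells in each library (points with replicate numbers, 6 control and 6 HALI), with group mean and SD (black bars). HALI replicate 5 has a neutrophil score of 5.48, where the other HALI libraries have 1.72 to 2.10.

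Markers of tissues next to the lung varied between libraries. Of 11 cardiac muscle genes, Sln fell and 10 did not pass, as when adjusted over the list alone (median -1.97, camera adjusted p = 0.14, 0.045 without control replicate 6). Sln had 1079 counts over the control and 34 over the HALI libraries, most of them in control replicate 5 (21.6 CPM), with a log2 fold change of -4.52 ± 1.18, and -3.50 without that library. Of 6 mesothelial genes, Lrrn4 (-1.34 ± 0.41) and Muc16 (-1.28 ± 0.44) fell and 4 did not pass, the same counts as adjusted over the list alone (median -0.96, camera adjusted p = 0.055). The camera p of this list ran from 0.018 to 0.092 when each library was left out and passed without control replicate 1, 2, 4 or 5 or HALI replicate 3 or 4. Lrrn4 missed the threshold without control replicate 2 or 3 or HALI replicate 1, 2, 5 or 6 (adjusted p up to 0.072) and had -0.86 without control replicate 6. Muc16 missed it without any library other than control replicate 1, control replicate 4 or HALI replicate 3 (up to 0.10) and had -0.76 without control replicate 6. Of 4 skeletal muscle genes, Mylpf (-0.64 ± 0.17) and Tnni2 (-0.85 ± 0.24) fell and 2 did not pass, the same counts as adjusted over the list alone (median -0.74, camera adjusted p = 0.36).

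Of 10 erythroid and platelet genes 0 passed in edgeR, also adjusted over the list alone, with 0 at an unadjusted p below 0.05, 0 called by DESeq2 and 1 called lower by limma-voom (median -0.37, camera adjusted p = 0.099). The camera test passed without HALI replicate 5 (adjusted p = 0.0070) or control replicate 2 (0.046), and without HALI replicate 5 Alas2, the erythroid enzyme of haem synthesis, had a log2 fold change of -1.10 (adjusted p = 0.0050) in place of -0.70 ± 0.35. Hbb-bs then had -0.92 (adjusted p = 0.0087) in place of -0.56 ± 0.32, and globin genes are near-copies of each other. Alas2 also passed on all libraries in limma-voom (0.0069) and with the replicate number as a block (0.044). Of 3 fat genes 0 passed in edgeR, also adjusted over the list alone, with 0 at an unadjusted p below 0.05 and 0 called by DESeq2 or limma-voom, and the median of -0.10 and mean of -0.43 were negative where the camera direction was higher (adjusted p = 0.92). Of the 2 genes of the thymus list measured, too few for a list test, Themis (-0.56 ± 0.18) fell, also adjusted over the list alone. T cells outside the thymus express Themis as well. Themis missed the threshold without control replicate 3 or 5 or HALI replicate 1, 3 or 6 (adjusted p up to 0.074). Of 5 sex-linked genes, Ddx3y (0.20 ± 0.06) and Eif2s3y (0.20 ± 0.07) were called higher and 3 did not pass, the same counts as adjusted over the list alone, with a median of 0.00 that was -0.05 with upper-quartile scaling (camera adjusted p = 0.61). Neither call held with upper-quartile scaling (adjusted p = 0.099 and 0.10). Ddx3y missed the threshold without control replicate 1 or 5 or HALI replicate 1, 4 or 6 (up to 0.069), and Eif2s3y without any library other than control replicate 3, control replicate 4 or HALI replicate 5 (up to 0.082).

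Among the 5 genes with the most counts, Scgb1a1, Sftpc, Lyz2 and the elongation factor gene Eef1a1 (-0.32 ± 0.08) fell, and mt-Co1 had a log2 fold change of 0.10 ± 0.11 (adjusted p = 0.51). Sftpc stood at 16082 ± 3394 CPM in control lungs and 11719 ± 1278 CPM in HALI lungs, and missed the threshold without HALI replicate 4 (adjusted p = 0.051).

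Across the 44 lists tested by camera, 8 were higher and 6 lower in HALI lungs, and 0 passed with an estimated correlation in place of the preset 0.01, where 2 had an unadjusted p below 0.05 and fry called 18 in a common direction. The number of lists called by camera was not unusual for these libraries, since 50 of 100 divisions of the 12 libraries into 6 and 6 gave at least 14, with a highest other count of 25. In an exact permutation of the list scores over the library labels, 2-sided and added after the data were seen, 15 lists passed an adjusted p of 0.05, 10 higher and 5 lower, where 0.002165 was the smallest p that the 924 reassignments allow. Those 15 held 10 of the 14 camera lists. The extracellular matrix (adjusted p = 0.16), club cell (0.21), T cell (0.15) and oxidative phosphorylation (0.056) lists did not pass. Without HALI replicate 5, 20 lists passed, which added the extracellular matrix (0.016), oxidative phosphorylation (0.040), transitional epithelium (0.043), neutrophil (0.0095) and erythroid and platelet (0.037) lists. Coagulation (0.029), iron handling (0.012), hypoxia (0.012), metallothionein and superoxide dismutase (0.029) and capillary endothelium (0.029) passed this test on all 12 libraries and not camera. Upper-quartile scaling ended the calls of Cldn5, Cpa3, Ddx3y, Egr2, Eif2s3y, Fth1, Ier2, Pfkfb3, Scnn1g, Sqle and Vcam1, and the size factors of DESeq2 ended those of Clic5 and Xbp1. With the replicate number as a block, 22 calls ended (adjusted p of 0.050 to 0.12), those of Cldn5, Clic5, Cox4i2, Cpa3, Cyp2f2, Ddx3y, Egfl7, Egr2, Fth1, Hopx, Ier2, Lrrn4, Ly6c2, Muc16, Mylpf, Pfkfb3, Tcf21, Themis, Tnc, Tnni2, Vwf and Xbp1. Without the low-count filter, with 38118 genes tested, 23 of the 157 named calls missed the threshold (Cldn5, Cpa3, Cxcl15, Cyp2f2, Ddx3y, Dnajb1, Dynlrb2, Egfl7, Egr2, Eif2s3y, Hp, Hspb1, Ier2, Junb, Lrrn4, Ly6c2, Muc16, Tcf21, Timp1, Tnc, Vcam1, Vwf and Xbp1).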

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

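The tests of clock phase, of the shared variation of the cardiac markers and of depth for the neutrophil genes were chosen only after the result was seen. Each named gene, list score and library measure was searched in each group of 6 for a library whose gap to the nearest other exceeded the 95% critical value of Dixon's test. Chance alone would single out about 1 in 20 groups, and 42 of 440 (9.55%) were singled out here, 33 genes, 6 list scores and 3 library measures. HALI replicate 5 held 17 of them, control replicate 4 held 8 and control replicate 2 held 6. Genes of a list are not independent of its score or of each other.

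HALI replicate 5 stood highest of the HALI libraries for Cxcr2 (81.0 CPM, others 3.14 to 4.90), Retnlg (99.8, others 2.48 to 3.82), Slc40a1 (46.4), Ednrb (99.8) and Tcf21 (117). It stood lowest for Eda2r (12.7, others 27.5 to 43.5), Ccn2 (210.35), Plau (8.98), Apln (51.3), Vcam1 (64.0), Hspa5 (416), Sdf2l1 (2.66), Pdia4 (87.9) and Dbp (8.58, others 34.2 to 70.7). Its mean log2 CPM was highest for the neutrophil list (5.48) and lowest for the extracellular matrix (6.26) and dendritic cell (2.53) lists.

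Control replicate 4 had the fewest counts (9.58 M) and genes with a count (25253) of the control libraries. It was lowest for Casp4 (11.5 CPM) and Sqle (37.5) and highest for Tcf21 (81.9), Egfl7 (394.61), Ier2 (44.0) and the immediate early list (mean log2 CPM 5.61). Control replicate 2 was highest for Cyp1a1 (426 CPM, others 49.6 to 103), Calcrl (2229) and the NRF2 list (6.12) and lowest for Mcm7 (25.5), Nr1d2 (133) and Eef1a1 (3490.2). Among the other control libraries, control replicate 1 was lowest for Tnfrsf10b (6.05), control replicate 5 for Ddx3y (131) and Fth1 (1153.9), control replicate 6 was highest for Icam1 (402), and control replicate 3 had the largest share in its 5 most abundant genes (6.70%). HALI replicate 3 was lowest of its group for Eppin (0.124 CPM) and highest for Sftpa1 (2510.2), Lyz2 (5024.5) and Fth1 (2010.2), and HALI replicate 6 was highest for Ier2 (63.4) and the immediate early list (6.69).

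The neutrophil genes of HALI replicate 5 came with lower values of many genes that rose in the other HALI lungs. A mixture with control RNA was argued against for the neutrophil genes. Their score of 5.48 lay above both the other HALI (1.72 to 2.10) and the control libraries (2.36 to 3.04). For genes that rose, the control share implied by each of 132 genes had an interquartile range of 0.497, where 30 simulated mixtures gave 0.161 to 0.291. The simulated mixtures averaged a HALI and a control library without drawing counts at the depth of HALI replicate 5. Their range can therefore be too narrow and does not decide for those genes. Depth was argued against for the neutrophil genes, whose score lay 3.41 above that of HALI replicate 2, a library of similar depth. Dilution by neutrophil RNA stays open as a part of the cause. S100a9, the most abundant of the 11 markers in HALI and chosen after its values were seen, stood at 65.0 ± 125 CPM there. An even dilution alone would lower all lung genes alike. Against the other HALI libraries, the 37 lung cell markers of HALI replicate 5 had a median difference of -0.0851 log2 units. The 268 genes at least 2-fold higher had -0.341, a difference between the sets of 0.256 (95% interval 0.128 to 0.469). Depth also stays open for the latter genes. The ratio of the shortfall of HALI replicate 2 to that of HALI replicate 5 was 0.647 (0.479 to 0.856). No biological explanation was tested. Both intervals came from resampling genes as if they were independent, and they hold no spread between libraries.

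The clock genes differed between the groups. Of the 13 called members that have a phase arm, 100% moved with it, as another hour of tissue collection could produce, and the labels do not state that hour. Without HALI replicate 5, 14 members passed, so the calls did not rest on that library alone. It lay closer to the controls than the other HALI libraries for several members, so leaving it out could hardly have ended their calls. An effect of hyperoxia on the clock stays open as untested, because hour and exposure cannot be separated in this design.

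Some heart muscle (1 of 11), club (4 of 9) and ciliated (2 of 11) markers were called lower in HALI lungs. The 11 cardiac markers varied together within groups (mean correlation 0.769, above the largest of 1000 random lists, 0.279). Markers of 1 cell type can do so in any tissue. The correlation that camera estimated was 0.77 for the cardiac, 0.93 for the mesothelial and 0.83 for the ciliated list, and lower for the other lists. The shared variation therefore cannot decide for carry-over. Myh6, chosen after its values were seen, stood at 125 ± 184 CPM in control and 10.8 ± 9.57 CPM in HALI lungs. Uneven carry-over of heart muscle stays a candidate explanation for their part. The cardiac score as a covariate could show only whether the club and ciliated fall went along with that score. Tissue carried over with heart muscle was argued against as the whole cause, since 4 of the 6 genes called lower still passed. Dynlrb2 among them shrank from -0.76 ± 0.21 to -0.50 ± 0.16. Cyp2f2 went from -0.59 ± 0.18 to -0.42 ± 0.16 and Hp from -0.54 ± 0.16 to -0.45 ± 0.16, so both calls ended with smaller changes and a similar spread. A change of the airway epithelium with hyperoxia stays open as untested.

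Chance was argued against for the number of genes called, since 1 of 100 divisions of the 12 libraries, the real one, gave as many. A division has no direction, so the larger count of its 2 directions was taken. This held for genes higher (2779, highest other 399), lower (2641, highest other 399), at least 2-fold higher (268, highest other 70) and at least 2-fold lower (412, highest other 70). For these counts, 1 in 100 is the smallest share that the divisions drawn can give, so chance was not excluded. Every other division held HALI and control libraries on both sides. Where the groups differ, this widens the spread within a side and lowers the number of genes called. Chance cannot be excluded either for the number of lists called by camera (14), which 50 of 100 divisions reached, with a highest other count of 25.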

How the results depend on the processing

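The cardiac covariate, the permutation of list scores and the joint omission of control replicate 5 and HALI replicate 5 were tests chosen only after the result was seen. All genes called both originally and under another scaling, filter, tool or design had the same sign. Called genes ranged from 4052 (replicate number as a block, 3960 of them shared with the 5420) to 6833 (limma-voom, 5273 shared). Genes at least 2-fold lower, 412 at first, numbered 643 without a filter, 262 with the stricter filter and 634 in DESeq2. DESeq2 was run without the filterByExpr filter and tested 23992 genes in place of 18701, so its gene set changed along with the tool. How much of these differences came from the genes added or removed was not tested. At an adjusted p of 0.01 there were 1607 genes higher and 1345 lower, as a stricter threshold allows fewer. Leaving out each library gave 2275 to 2928 genes higher, 2096 to 2838 lower, 256 to 303 at least 2-fold higher and 370 to 512 at least 2-fold lower.

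Camera called 14 lists, 13 to 21 when each library was left out, 18 with the replicate block, and 0 with an estimated correlation (2 at an unadjusted p below 0.05), while fry called 18 by direction and 33 mixed, and permutation 15. The groups overlapped on the first component over the 500 most variable genes (gap -6.10%); the cause was not tested. Cxcr2 (-0.57 to 1.68) and Retnlg (-1.02 to 1.79) reversed without HALI replicate 5, and had -0.66 and -1.12 without both replicates 5, since the neutrophil genes were high in that library.

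Of 169 named genes 157 were called, 116 of them under each of the 22 settings and 0 with a reversal; leaving out 1 library ended 32 calls at least once, scaling 14, the block 22, limma-voom 2 (Cldn4 and Pfkfb3), DESeq2 0, the cardiac covariate 22 and leaving out both replicates 5 together 15. Library totals of 9.58 to 33.7 M limit genes with few counts.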

Other observations

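The families, their grouping by symbol and their permutation tests were chosen only after the result was seen. A family held the protein-coding genes with the same letters before the first digit of the symbol, so its name need not describe every member. Several families with members in ribosome assembly and translation initiation had more members called higher than lower in HALI lungs, by small amounts. Among other families of translation that did not pass the permutation test were the ribosomal protein families Rpl (1 higher and 1 lower of 48, permutation adjusted p = 0.99) and Rps (5 higher and 1 lower of 43, 0.53), the elongation factors Eef (4 higher and 1 lower of 12, 0.98) and the mitochondrial ribosomal protein families Mrpl (10 higher and 1 lower of 48, 0.20) and Mrps (6 higher and 1 lower of 29, 0.20). The median of Rps (0.04) was -0.01 with upper-quartile scaling. Of 54 measured genes of the family Eif, which holds regulators of initiation beside the initiation factors, 28 rose and 3 fell, with a median log2 fold change of 0.20. Among nucleolar families, 5 of 8 Rrp (median 0.38), 5 of 8 Nop (0.28), 5 of 10 Utp (0.25) and 5 of 9 Nol genes (0.29) rose. The RNA helicase family Ddx (17 higher, 2 lower of 36, median 0.15), the nucleoporins Nup (10 higher, 1 lower of 21, 0.21) and the proteasome family Psmd (8 higher of 14, 0.15) followed, while the proteasome families Psma (2 higher of 8, permutation adjusted p = 0.19) and Psmb (3 higher of 10, 0.24) did not pass. Of 20 protocadherins Pcdhb, 11 rose (0.47), while Pcdhga (3 higher of 11) did not pass (permutation adjusted p = 0.071), although reads shared between these near-copies were not examined.

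Of 16 histone genes (Hist), 7 fell (median -0.69), and many histone transcripts carry no polyA tail, so this selection holds only part of them. Calls were also more often lower among the protease inhibitor family Wfdc (6 of 9, -0.71), the guanylate-binding proteins Gbp (4 of 9, -0.45) and the cytochrome P450 genes Cyp (10 lower, 2 higher of 35, -0.25). The 13 families given here that passed were taken from 248 families of at least 8 members, of which 65 passed an exact permutation of their mean log2 CPM. The adjusted p was 0.027 for Psmd, 0.033 for Pcdhb, 0.045 for Gbp (0.071 without HALI replicate 5) and 0.019 for the other 10, while camera with an estimated correlation gave 0.62 or higher for all 13. No median of these 13 families changed sign under the other scalings.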
